A study of Rattus norvegicus with 6 samples.

How the data were processed

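Gene expression was measured on Affymetrix rat gene arrays hybridised with RNA from primary rat oligodendrocyte progenitor cells (OPCs), the dividing glial cells of the brain that give rise to the oligodendrocytes that make myelin. Per the labels' protocols, cells came from rat pups of postnatal day 1 to 2, recovered for 2 days in medium with the growth factors PDGF and NT3, and fibrinogen, the blood clotting protein, was then given for 48 h in differentiation medium. The controls are labelled unstimulated with the same 48 h in their titles, and their medium is not stated. RNA was purified on columns with DNase treatment, amplified with a NuGEN whole-transcriptome kit and labelled with biotin, per the labels' protocols. There were 6 arrays in 2 groups, 3 unstimulated (control) and 3 fibrinogen-treated, grouped by their titles.

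The file holds the authors' deposited log2 expression values, 1 column per array and 1 row per probe set, rounded to 2 decimals. RMA (background correction, quantile normalization and summary of the probes of a probe set) and limma are named in the submitters' processing notes, without versions or settings, and the steps behind the values are otherwise not given in the sources used here. Of 26312 probe rows, 23631 have a value on every array and 2681 are empty on every array; no reason is given in the sources used here. The array medians over the valued probes lie between 5.78 and 5.84 and the values run from 1.36 to 13.14, so they are normalized between arrays and not centred per gene. RMA compresses large changes of dim probes, and no detection call accompanies the values, so whether a dim probe lies above background is unknown. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.104. No build is given in the sources used here, so no coordinates are printed.

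Probes were named from the platform's annotation, which lists 15417 of the probes: 15094 with 1 gene symbol and 323 with several. Of the 14083 valued probes with 1 symbol, 14059 matched a current rat gene record by gene number, and no symbol needed updating. Each gene was represented by its probe with the highest mean over all arrays, which gave 13355 genes, 462 of them with more than 1 probe. Of the 34 called genes with more than 1 probe, 3 had a probe of the opposite sign. The 228 valued probes with several symbols and the 9320 valued probes with no listed name entered no gene-level test.

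Fibrinogen was compared with control in limma 3.58.1 (R 4.3.3; lmFit and eBayes, two-sided, no covariate, no filter on dim probes), with the Benjamini-Hochberg adjusted p over all 13355 genes and a threshold of 0.05. Fold changes are fibrinogen over control on the log2 scale, errors are moderated standard errors (SE) or standard deviations over the 3 arrays of a group (SD), and intervals are 95%. Adjusted p-values of genes below are from this fit. Before the data were examined, 23 lists of genes (480 memberships, 405 measured) were fixed from textbook knowledge: BMP-SMAD target genes, BMP ligands and receptors, TGF-beta and fibrosis-associated genes, myelin and mature oligodendrocyte genes, cholesterol synthesis, oligodendrocyte progenitor genes, astrocyte markers, reactive astrocyte genes, markers of microglia, neurons, endothelium, pericytes and fibroblasts and Schwann cells, cell cycle, interferon response, NF-kB, Notch and Wnt genes, stress genes, immediate early genes, fibrinogen receptors and fibrinolysis, chondroitin sulfate proteoglycans and matrix, and glycolysis and hypoxia. Members without a valued probe of a single symbol were not analysed here. The series' own title names BMP signaling, so the BMP-SMAD list restates the study's question and is no independent pick. Lists were tested with camera in limma (preset inter-gene correlation of 0.01, Benjamini-Hochberg over the 23 lists); camera with an estimated correlation and fry were alternatives. A list score is the mean log2 value of a list's measured members on an array. Scores were compared with a two-sided exact permutation test, which cannot go below 0.1 with 3 arrays against 3.

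The genes named were set by rule before the data were examined: the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap (leaving out symbols of uncharacterised loci and olfactory, vomeronasal, immunoglobulin and histone genes), up to 4 members per list with the smallest p, and 18 genes named whatever their values, of which 13 were measured. Genes ranked 9 to 20 in each direction were kept for the closing section. Other genes named are said to have been chosen afterwards. The model was tested on simulated arrays for the 13355 genes of this comparison, with the real means and the moderated variances of the fit. Moderated variances are drawn toward a common value and spread less than the genes' own. Each setting was simulated once, so the rates below may be optimistic. With 200 changed genes it called 48.7% of those changed by 0.5 on the log2 scale, 98.4% of those changed by 1 and 100% of those changed by 2, with 3.61% false calls among all calls. Simulated arrays with no change gave 0 called genes and 0 called lists, and 1 list shifted among changed genes gave 2 called lists. The simulated genes varied independently of each other, so these list counts do not cover lists whose genes vary together. On the real arrays the estimated correlation within a list reached 0.308, for the oligodendrocyte progenitor genes.

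The labels give no batch, date or litter, and do not say that arrays came from separate cultures, so p-values measure the spread between these arrays, which may be partly technical. All pairs of arrays differed: at most 2.53% of probes had equal values on any pair. Correlations over probes were 0.990 to 0.994 within groups and 0.985 to 0.991 between groups. Control 1 had the lowest between-group values (0.9853 to 0.9872). Its correlation with control 2 (0.9897) lay below that of control 2 with fibrinogen 2 (0.9902). Alternatives changed the block, the probe rule, the brightness filter, the scaling, the variance model, the array weights, the test and the threshold, and left out each array in turn.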

Results

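Transcript levels of 13355 genes were compared between 3 arrays of unstimulated rat OPCs (control) and 3 arrays of OPCs that received fibrinogen for 48 h. The series title poses the question of whether fibrinogen, a plasma protein that enters the brain when vessels are damaged, activates BMP signaling in OPCs and holds back myelin repair. In total 956 genes (7.16% of those tested) passed an adjusted p of 0.05 in limma, of which 555 were higher and 401 lower with fibrinogen. Changes were mostly modest: 60 of these genes changed at least 2-fold, 37 upward and 23 downward. With each array centred on its own median, which lowers the median change of all genes from 0.003 to -0.043 on the log2 scale, the split was 434 higher and 516 lower. The groups did not overlap for 27.0% of genes, against 10% expected by chance with 3 arrays against 3. Leaving out 1 array lowered the count of called genes to 566, 592 and 467 without control 1, 2 and 3, and to 358, 378 and 393 without fibrinogen 1, 2 and 3.

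The 8 largest rises by the naming rule included 3 genes of extracellular matrix proteins (Bgn, Mfap4 and Mgp). Tagln2 (transgelin 2, an actin-binding protein; probe set 10765772) stood at a log2 expression of 7.02 ± 0.32 (SD, n = 3) in control and 9.39 ± 0.12 (SD, n = 3) in fibrinogen cultures, a 5.16-fold rise (log2 fold change 2.37, SE 0.16, adjusted p = 0.00141). Bgn (biglycan, a matrix proteoglycan; 10935890) rose 4.25-fold from 6.17 ± 0.13 to 8.26 ± 0.29 (SD, n = 3). Lxn (latexin, a carboxypeptidase inhibitor; 10823548) rose 3.66-fold, and the homeobox gene Dbx2 (10906569) rose 3.05-fold. Mfap4 (a microfibril-associated protein; 10734242), Mgp (matrix Gla protein, an inhibitor of BMP ligands and calcification; 10866512), Pmepa1 (a target and inhibitor of TGF-beta signaling; 10852144) and Emp1 (epithelial membrane protein 1; 10859296) rose 3.03-, 3.01-, 3.00- and 2.98-fold. The mean control levels of Mfap4, Mgp and Emp1 lay below the median probe of the arrays. All 8 kept their call with any one array left out (highest adjusted p = 0.0400, for Mfap4). Mfap4 and Mgp lost their call with the unmoderated test (adjusted p = 0.0716 and 0.0609).

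The 8 largest falls included the enzyme genes Ehhadh, Papss2 and Acss2 and the transporter gene Slc6a6. Tmprss11f (a transmembrane serine protease; 10772020) fell 3.97-fold from a log2 expression of 5.64 ± 0.45 to 3.65 ± 0.27 (SD, n = 3), with both levels below the median probe of the arrays (log2 fold change -1.99, SE 0.24, adjusted p = 0.00487). Samd5 (10716704) fell 2.74-fold, Ehhadh (a peroxisomal fatty acid oxidation enzyme; 10752081) 2.57-fold and Pnkd (10924274) 2.57-fold. Slc6a6 (the taurine transporter; 10857314) fell 2.52-fold from 9.47 ± 0.05 to 8.13 ± 0.04 (SD, n = 3). Papss2 (which makes the sulfate donor PAPS; 10714818) fell 2.49-fold, Tgfb2 (a TGF-beta ligand; 10770577) 2.42-fold, and Acss2 (cytosolic acetyl-CoA synthetase; 10841348) 2.39-fold from 10.11 ± 0.03 to 8.85 ± 0.10 (SD, n = 3). All 8 kept their call with any one array left out (highest adjusted p = 0.0301, for Tmprss11f). Tmprss11f lost its call with the unmoderated test (adjusted p = 0.0603).

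Of the 17 measured BMP-SMAD target genes, 3 rose and 14 did not pass the test; 14 of the 17 had a positive change. Id1, an inhibitor of differentiation that BMP receptors induce through SMAD proteins, rose 1.5-fold from a log2 expression of 7.61 ± 0.12 to 8.19 ± 0.08 (SD, n = 3; log2 fold change 0.58, SE 0.09, adjusted p = 0.0120). Hes1, a transcriptional repressor downstream of both BMP and Notch signaling, rose 2.08-fold (adjusted p = 0.00272), and Hey1, another such repressor, rose 1.53-fold (adjusted p = 0.0292). The other Id genes did not pass: the log2 fold change was 0.25 for Id2 (SE 0.07, adjusted p = 0.0917), 0.07 for Id3 (95% interval -0.15 to 0.28) and 0.19 for Id4 (95% interval -0.12 to 0.50). The inhibitory SMAD genes, also BMP targets, were at 0.12 for Smad6 and 0.08 for Smad7 (95% intervals -0.07 to 0.31 and -0.33 to 0.49). In control arrays, 9 of the 17 members lay below the median probe, Hes1, Smad6 and Smad7 among them. Adjusted over the list alone, 4 members rose. The list as a whole ranked above other genes (median log2 fold change 0.19, camera adjusted p = 0.00379), but not with an estimated correlation (adjusted p = 0.106) or without genes below the median brightness (adjusted p = 0.0646). This list restates the question in the series title and is no independent pick. The call of Id1 was lost without fibrinogen 3 (adjusted p = 0.0539) and with the unmoderated test (adjusted p = 0.0529). That of Hey1 was lost without any one array other than control 1 (highest adjusted p = 0.110, without fibrinogen 1).

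Among 22 measured BMP ligands, receptors and signal transducers, 2 rose, 2 fell and 18 did not pass. The ligand genes Bmp2 and Bmp4 fell by 0.94 (SE 0.14, adjusted p = 0.0107) and by 0.45 (adjusted p = 0.0133) on the log2 scale, while Rgma, a BMP co-receptor, and Fstl1, a secreted follistatin-like protein, rose by 0.65 and 0.36 on that scale (adjusted p = 0.0229 and 0.0351). The type I receptor gene Acvr1 was at 6.91 ± 0.07 in control and 7.05 ± 0.07 (SD, n = 3) with fibrinogen, a log2 fold change of 0.14 (95% interval -0.04 to 0.33). The list did not pass the test against other genes (camera adjusted p = 0.635), and adjusted over the list alone 3 members rose and 2 fell. The call of Bmp2 was lost without fibrinogen 1 (adjusted p = 0.0536) and with the unmoderated test (adjusted p = 0.0777). That of Bmp4 was lost without control 3 or any fibrinogen array (highest adjusted p = 0.0616). That of Rgma was lost without any one array other than fibrinogen 2 and that of Fstl1 without any one array (highest adjusted p = 0.0924 and 0.122).

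Myelin and mature oligodendrocyte genes were lower with fibrinogen: 16 of 28 measured members fell, 1 rose and 11 did not pass. Fa2h (fatty acid 2-hydroxylase, which makes hydroxylated myelin lipids) fell 1.87-fold from a log2 expression of 9.53 ± 0.06 to 8.63 ± 0.03 (SD, n = 3; adjusted p = 0.00166), Adamts4 (a proteoglycan-cleaving protease of oligodendrocytes) 1.88-fold and Enpp6 (a choline phosphodiesterase of newly forming oligodendrocytes) 1.73-fold. Mag (myelin-associated glycoprotein) fell 1.55-fold, by 0.63 on the log2 scale (SE 0.08, adjusted p = 0.00563). Mbp (myelin basic protein) fell 1.32-fold from 11.95 ± 0.13 to 11.55 ± 0.07 (SD, n = 3; adjusted p = 0.0468). Mog (myelin oligodendrocyte glycoprotein), at 7.73 ± 0.13 in control and 7.60 ± 0.06 (SD, n = 3) with fibrinogen, did not pass (log2 fold change -0.12, 95% interval -0.34 to 0.09). Ermn (ermin, a cytoskeletal protein of mature oligodendrocytes) went the other way and rose 2.83-fold from 5.0 ± 0.05 to 6.50 ± 0.29 (SD, n = 3; adjusted p = 0.00264). Its control level lay below the median probe of the arrays. The list as a whole was lower (median log2 fold change -0.37, camera adjusted p = 5.27e-11) and stayed so with an estimated correlation (adjusted p = 0.0445). Adjusted over the list alone, 16 members fell and 1 rose. The call of Mbp was lost without any one array (adjusted p = 0.0638 without control 2 to 0.156 without fibrinogen 1), and with the mean of the 2 Mbp probes (adjusted p = 0.0807).

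Cholesterol synthesis genes fell together: 15 of 18 measured members fell, 3 did not pass, and all 18 changes were negative. Cholesterol is a main lipid of myelin, and its synthesis genes are under common transcriptional control. Tm7sf2 (a sterol reductase) fell 2.13-fold and Mvd (mevalonate diphosphate decarboxylase) 2.21-fold, from a log2 expression of 9.68 ± 0.07 to 8.54 ± 0.11 (SD, n = 3; adjusted p = 0.00162). Nsdhl (a sterol dehydrogenase) fell 1.58-fold and Idi1 (isopentenyl-diphosphate isomerase) 1.52-fold (adjusted p = 0.00486 and 0.00489). The median log2 fold change was -0.59 (camera adjusted p = 5.53e-18, and adjusted p = 0.0445 with an estimated correlation), and 17 members fell when adjusted over the list alone. The mean score of the list was 10.01 ± 0.05 in control and 9.44 ± 0.03 (SD, n = 3) in fibrinogen arrays, without overlap (two-sided exact permutation p = 0.1, the smallest possible).

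**Figure D1:**
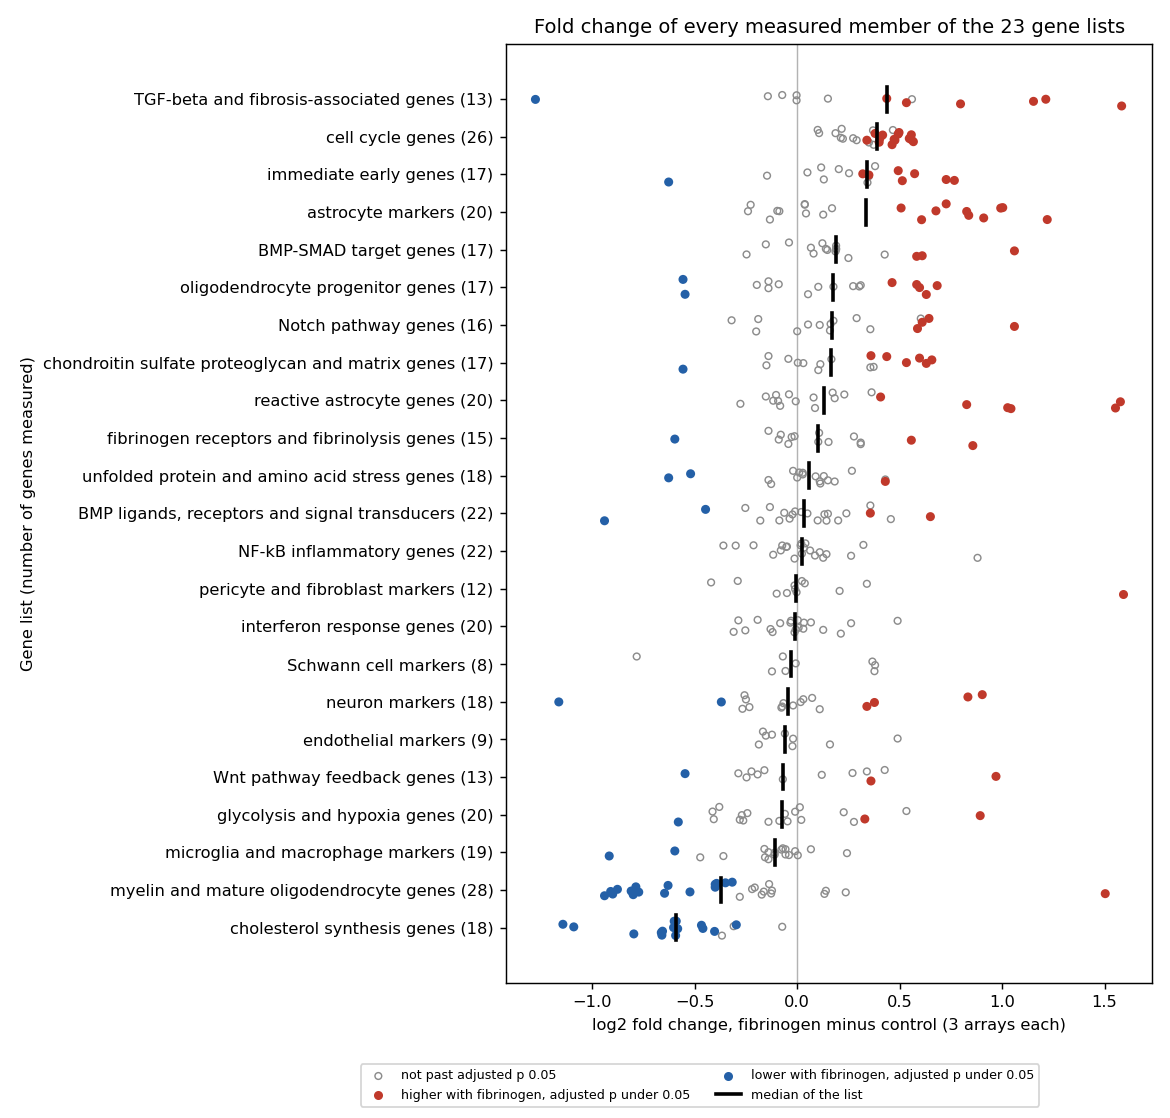
Log2 fold change (x axis, fibrinogen minus control, 3 arrays each) of every measured member of the 23 gene lists (y axis, number of measured genes in brackets); filled points passed an adjusted p of 0.05, red higher and blue lower, open points did not, and bars mark list medians. The cholesterol list lies wholly below 0 (median -0.59), the myelin list has 1 member, Ermn, far to the right of the others, and the cell cycle list lies wholly above 0 (median 0.39).

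Oligodendrocyte progenitor genes moved both ways: 5 of 17 measured members rose, 2 fell and 10 did not pass. Cspg4 (the NG2 proteoglycan of progenitors) rose 1.55-fold from a log2 expression of 7.87 ± 0.04 to 8.50 ± 0.07 (SD, n = 3; adjusted p = 0.00493), C1ql1 (a secreted C1q-like protein) 1.61-fold and Cspg5 (neuroglycan C) 1.51-fold. Pdgfra, the PDGF receptor of progenitors, rose 1.5-fold from 10.08 ± 0.13 to 10.67 ± 0.01 (SD, n = 3; adjusted p = 0.010). Sox10, a transcription factor of the whole oligodendrocyte lineage, was at 9.27 ± 0.07 and 9.18 ± 0.06 (SD, n = 3) and did not pass (log2 fold change -0.09, 95% interval -0.27 to 0.09). The list's median log2 fold change was 0.18 (camera adjusted p = 0.0415), with adjusted p = 0.649 with an estimated correlation, and 7 members rose and 2 fell adjusted over the list alone. The list call was lost without control 1 (adjusted p = 0.119), fibrinogen 1 (adjusted p = 0.0707) and fibrinogen 2 (adjusted p = 0.0869), and that of Pdgfra without fibrinogen 1 (adjusted p = 0.0504).

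Astrocyte markers were higher with fibrinogen: 10 of 20 measured members rose and 10 did not pass. Gfap, the intermediate filament gene of astrocytes, rose by 1.00 on the log2 scale, from 9.68 ± 0.07 to 10.68 ± 0.03 (SD, n = 3; SE 0.07, adjusted p = 0.00162). Atp1b2 (a sodium pump subunit) rose 1.88-fold, Vim (vimentin, another intermediate filament) 1.77-fold and Cd44 (a hyaluronan receptor) 1.65-fold. The water channel gene Aqp4 and the gap junction gene Gja1, chosen after their values were seen, were at -0.24 and -0.10 on the log2 scale (95% interval -0.51 to 0.03 for Aqp4 and -0.29 to 0.09 for Gja1) and did not pass. The list's median log2 fold change was 0.34 (camera adjusted p = 7.27e-06, and adjusted p = 0.0445 with an estimated correlation), and adjusted over the list alone 10 members rose. Of 20 reactive astrocyte genes, 6 rose and 14 did not pass, with the same counts adjusted over the list alone. The rises included Emp1, Hspb1 (a small heat shock protein, 2.93-fold), S100a10 (an annexin partner, 2.06-fold) and Timp1 (a metalloprotease inhibitor, 1.77-fold). In control arrays, 16 of the 20 reactive astrocyte genes lay below the median probe. That list's call (camera adjusted p = 0.00511) was lost with an estimated correlation (adjusted p = 0.106) and without Emp1 and Hspb1 (adjusted p = 0.131), an alternative chosen after seeing the data.

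Cell cycle genes were higher with fibrinogen: 14 of 26 measured members rose, 12 did not pass, and all 26 changes were positive. The named members act in mitosis. Nusap1 (a spindle protein) rose 1.48-fold from a log2 expression of 8.30 ± 0.02 to 8.87 ± 0.12 (SD, n = 3; adjusted p = 0.0108), Tpx2 (a spindle assembly factor) 1.47-fold, Plk1 (a mitotic kinase) 1.39-fold and Ccnb2 (cyclin B2) 1.46-fold. The median log2 fold change was 0.39 (camera adjusted p = 1.56e-14, and adjusted p = 0.0445 with an estimated correlation), and 22 members rose adjusted over the list alone. The calls of Nusap1, Tpx2 and Plk1 were lost without fibrinogen 2 (adjusted p = 0.0518, 0.0518 and 0.0541). That of Ccnb2 was lost without fibrinogen 1 or 3 (adjusted p = 0.0576 and 0.0539). Of 17 immediate early genes, 7 rose, 1 fell and 9 did not pass (camera adjusted p = 3.16e-05, and adjusted p = 0.0445 with an estimated correlation; 10 rose and 1 fell adjusted over the list alone). Egr1 and Egr3, transcription factors induced by growth factors, rose 1.70-fold and 1.43-fold and Ier2 rose 1.65-fold. Atf3, a stress-induced transcription factor, fell 1.54-fold (adjusted p = 0.00564). The call of Ier2 was lost without control 2 or any fibrinogen array (highest adjusted p = 0.0900).

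**Figure D2:**
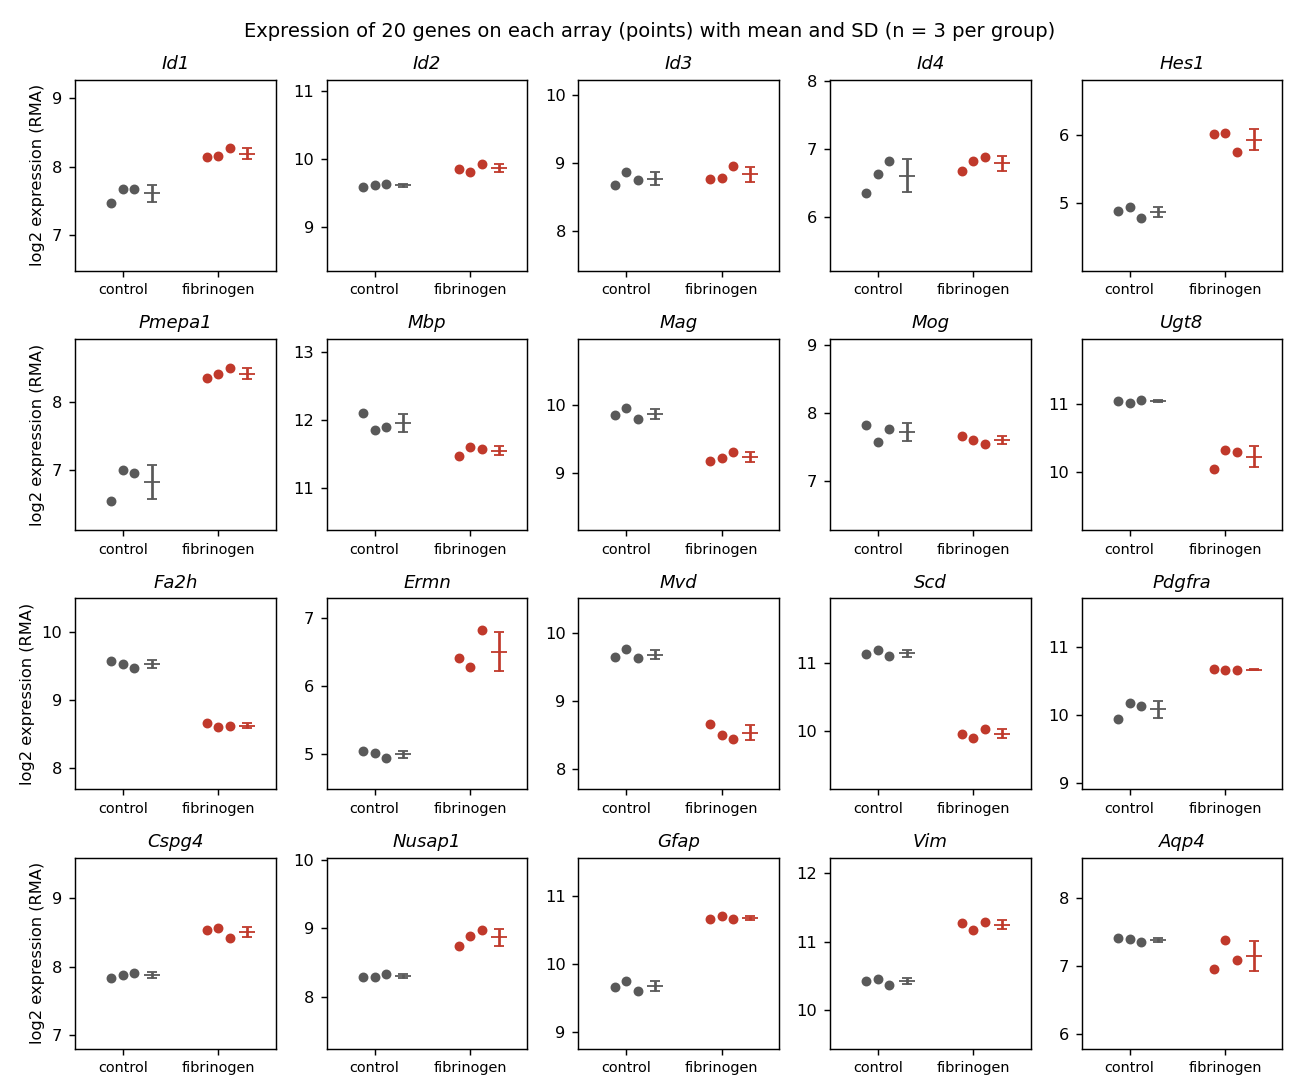
Log2 expression (y axis, RMA values; every panel spans 2.8 log2 units) of 20 genes on each of the 3 control arrays (grey) and 3 fibrinogen arrays (red); points are arrays, and horizontal marks with bars are the mean and SD. Hes1, Pmepa1, Ermn and Gfap are higher and Fa2h, Mag, Mvd and Scd lower on all 3 fibrinogen arrays, while Id3, Mog and Aqp4 did not pass the test; Ugt8 and Aqp4 were chosen after their values were seen.

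TGF-beta and fibrosis-associated genes changed in both directions: 6 of 13 measured members rose, 1 fell and 6 did not pass. Pmepa1, Tagln (transgelin, an actin-binding protein of contractile cells, 2.32-fold) and Ccn1 (a matricellular protein, 2.22-fold) rose, whereas Tgfb2 fell. The list's call (median log2 fold change 0.44, camera adjusted p = 0.00183; 7 rose and 1 fell adjusted over the list alone) was lost with an estimated correlation (adjusted p = 0.149). Of 17 chondroitin sulfate proteoglycan and matrix genes, 6 rose, 1 fell and 10 did not pass (camera adjusted p = 0.00379, and adjusted p = 0.236 with an estimated correlation; 8 rose and 1 fell adjusted over the list alone). Ncan (neurocan, a brain matrix proteoglycan) rose 1.58-fold beside Cspg4 and Cspg5, and Tnr (tenascin R) fell 1.47-fold. The call of Tnr was lost without fibrinogen 1 or 3 (adjusted p = 0.0566 and 0.0533). Of 16 Notch pathway genes, 4 rose and 12 did not pass: Hes1, Hey1, the receptor Notch1 (1.5-fold) and the feedback inhibitor Nrarp (1.56-fold). That call (camera adjusted p = 0.0109; 5 rose and 1 fell adjusted over the list alone) was lost with an estimated correlation (adjusted p = 0.112) and without Hes1 and Hey1, which belong to other lists too (adjusted p = 0.113). The calls of Notch1 and Nrarp were lost without any one of control 1, control 3, fibrinogen 1 and fibrinogen 3, and for Notch1 also fibrinogen 2 (highest adjusted p = 0.0748 and 0.0795).

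Of 19 microglia and macrophage markers, 17 lay below the median probe in control arrays; Itgam (the fibrinogen-binding integrin alpha M) fell 1.51-fold and Cd53 (a leukocyte tetraspanin) 1.89-fold, and 17 did not pass. Csf1r and Fcer1g, at -0.36 and 0.24 on the log2 scale, were among the latter. That list's call (camera adjusted p = 0.0415; 2 fell adjusted over the list alone) was lost with an estimated correlation (adjusted p = 0.160), without control 1 (adjusted p = 0.143), without fibrinogen 1 (adjusted p = 0.0748) and without the dimmest 25% of probes (adjusted p = 0.724). The call of Itgam was lost without any one array other than control 1, and that of Cd53 without control 1, control 3, fibrinogen 1 or fibrinogen 2 (highest adjusted p = 0.122 and 0.130). Neuron markers went both ways (4 of 18 rose, 2 fell, 12 did not pass, camera adjusted p = 0.788; 4 rose and 5 fell adjusted over the list alone): Elavl4 (a neuronal RNA-binding protein) and Stmn3 (a stathmin) rose 1.87- and 1.78-fold, and Syt1 (synaptotagmin 1) fell 2.24-fold. Elavl3 fell 1.29-fold, a call lost without any one array (highest adjusted p = 0.104). The call of Stmn3 was lost with the unmoderated test (adjusted p = 0.0529). Of 12 pericyte and fibroblast markers, Mgp rose and 11 did not pass, among them Postn, Igfbp5 and Dcn at -0.42, 0.34 and -0.29 on the log2 scale (camera adjusted p = 0.829; 1 rose and 1 fell adjusted over the list alone). The 9 endothelial markers and 8 Schwann cell markers gave 0 calls in limma over all genes and 0 with the unmoderated test. At an unadjusted p under 0.05 were 1 and 3 of them, and 9 and 6 lay below the median probe in control arrays. Their camera adjusted p-values were 0.833 and 0.829, and adjusted over the list alone 0 endothelial markers changed and 1 Schwann cell marker rose and 1 fell.

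Inflammatory lists gave 0 calls: the 20 interferon response genes and 22 NF-kB inflammatory genes had 3 and 3 members at an unadjusted p under 0.05, and 0 calls with the unmoderated test or adjusted over the list alone (camera adjusted p = 0.800 and 0.917). Most members, 15 and 17 respectively, lay below the median probe in control arrays. The largest change among their named members was in the chemokine gene Ccl2, at 0.88 on the log2 scale with a 95% interval of 0.10 to 1.66 (adjusted p = 0.183). The remaining lists did not pass camera's test against other genes. Of 15 fibrinogen receptor and fibrinolysis genes, F3 (tissue factor) rose 1.81-fold and Plat (tissue plasminogen activator) 1.47-fold, Itgam fell and 12 did not pass (camera adjusted p = 0.175; 3 rose and 1 fell adjusted over the list alone). Of 13 Wnt feedback genes, Sfrp1 (a secreted Wnt modulator, 1.96-fold) and Ccnd1 (cyclin D1, 1.28-fold) rose and Lgr5 (an R-spondin receptor) fell 1.46-fold (camera adjusted p = 0.829; 2 rose and 1 fell adjusted over the list alone). Of 18 stress genes, Cebpb rose 1.35-fold and Atf3 and Ddit4 fell, Ddit4 by 1.43-fold (camera adjusted p = 0.70; 2 rose and 2 fell adjusted over the list alone). Of 20 glycolysis and hypoxia genes, Egln3 (a hypoxia-induced prolyl hydroxylase, 1.86-fold) and Eno1 (enolase, 1.26-fold) rose and Bnip3 (a mitophagy receptor) fell 1.5-fold (camera adjusted p = 0.352; 4 rose and 5 fell adjusted over the list alone). The calls of Ccnd1, Lgr5, Cebpb and Eno1 were lost without any one array, that of Plat without any one other than control 2 and that of Ddit4 without any one other than fibrinogen 2 (highest adjusted p = 0.141, for Plat). The calls of Plat, Eno1, Fstl1, Cebpb and Ccnd1 were also lost with each array centred on its median (adjusted p = 0.0504, 0.0556, 0.0566, 0.0574 and 0.0582). Median and mean differed in sign for the Wnt, pericyte and fibroblast, and Schwann cell lists, with medians of -0.07, -0.01 and -0.03 and means of 0.06, 0.11 and 0.01 on the log2 scale.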

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

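The tests of contaminating astrocytes and of a lower share of lineage cells were chosen only after the results were seen. Among the 9320 valued probes that have no gene name here, which enter no comparison in the report, 36 were at least 2-fold higher with fibrinogen than in the control arrays at an adjusted p under 0.05, and 7 were at least 2-fold lower. In all 267 of these probes passed (170 higher, 97 lower), or 2.86%, and the share of named genes was 7.16%. The adjusted p-values of these probes do not come from the fit of the named genes. The same threshold can thus stand for different unadjusted p-values, and the shares are not directly comparable. The median log2 brightness was 5.22 for these probes against 6.32 for named genes. These probes are unnamed here, and which of them measure a gene was not determined.

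The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split, 1 of the 10, gave 956 genes against at most 0 in the other splits, 60 genes changed at least 2-fold against at most 0, and 12 gene lists against at most 6.

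Astrocyte markers rose with fibrinogen (median log2 change 0.34). A trend of fold change with brightness is argued against, since the median lay at percentile 100 of 10000 random lists matched on brightness (95% range -0.07 to 0.11). More contaminating astrocytes would raise all markers as much as Gfap only if astrocytes alone express them. That was not measured, so the test of this cause cannot decide. Of 11 members between the median probe and Gfap in brightness, 6 had a 95% interval wholly below that of Gfap. This was the outcome set, after the results were seen, against astrocytes as the whole cause. The lower bound of Gfap was 0.83, and the 6 were Aqp4 at -0.24, Gja1 -0.10, S100b -0.09, Acsbg1 0.04, Fgfr3 0.51 and Slc1a3 0.61. The other 5 rose by 0.68 to 1.22, so added astrocytes, as the whole cause or a part, stay open. An effect of fibrinogen on the OPCs themselves stays open too, as untested on these arrays of whole cultures.

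Myelin and cholesterol synthesis genes fell (median log2 changes -0.37 and -0.59) while cell cycle genes rose (0.39). A brightness trend is argued against: the medians lay at percentiles 0, 0 and 100 of matched random lists, whose 95% ranges were -0.05 to 0.09, -0.06 to 0.09 and -0.06 to 0.10. If Olig1 and Sox10 kept their level per cell, a lower share of oligodendrocyte lineage cells would not explain the whole myelin fall. That level was not measured, and both genes are on the progenitor list, so a lower share stays open. These 2 lineage genes moved apart: Olig1 rose by 0.46 and Sox10, at -0.09, did not pass. Both 95% intervals (0.30 to 0.63 and -0.27 to 0.09) and that of their mean, 0.19 (0.03 to 0.35), lie above the myelin median. A different mix of stages within the lineage and an effect of fibrinogen on it stay open, as untested. As the medium of the controls is not stated, a difference in medium cannot be told apart from fibrinogen, here or for other lists.

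BMP-SMAD target genes rose as a list (adjusted p = 0.00379), but not with an estimated correlation (0.106), and 4 of its 17 members also belong to the Notch or Wnt list. Those 4 had a median log2 change of 0.52, against 0.15 for the other 13. The 13 alone had an adjusted p of 0.0379 on all arrays, the outcome written beforehand for a rise that the shared members do not carry, but 0.328 with an estimated correlation. With the preset correlation it ranged from 0.0176 to 0.111 without one array, a check chosen after the results were seen, so whether the shared members carry the rise cannot be told. Whether fibrinogen activates BMP signaling, the question of the series title, stays open, since RNA levels do not measure the activation of BMP receptors.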

How the results depend on the processing

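The count of genes changed, 956, became 343 with the replicate number as a block (332 of them among the 956), 1508 without probes below the median brightness, 1617 with an intensity trend and robust prior, 185 when tested against a 1.2-fold change, 500 with the unmoderated test, 279 at an adjusted p under 0.01, and 358 to 592 without one array. Same-numbered arrays correlated at 0.02, -0.14 and -0.07 in their deviations, and no array correlated best with its own number. These values show no pairing by number, but so few pairs cannot exclude a weak one, and the labels do not state any. Of the 74 called named genes the block ended 20 calls, the unmoderated test 19 and the test against 1.2-fold 32. Over all probes, named or not, 104 probes changed at least 2-fold, a count of probes, while the 60 genes changed at least 2-fold count each gene once. Called lists, 12 in number, became 7 without probes below the median brightness (19 lists tested), 5 with an estimated correlation and 6 without the 2 members of smallest p, an alternative chosen after seeing the data. The adjusted p of the list BMP-SMAD target genes was 0.0646, 0.106 and 0.0802 under these. That of the list oligodendrocyte progenitor genes was 0.177, 0.649 and 0.303 under these, 0.0884 with the block, 0.102 without the dimmest 25% of probes, 0.0772 with quantile normalization again, 0.0620 with array weights, 0.0630 with members in no other list, and 0.0284 to 0.119 without one array. The Notch and proteoglycan lists were also lost without probes below the median brightness, and the microglia list with quantile normalization, centring, a trend prior, array weights and fry. Lists with non-overlapping scores were 9 in place of 14 with the median of members, which turned the score differences of reactive astrocyte genes to -0.052 and of immediate early genes to -0.127. That median falls on different genes in different arrays, so these 2 values do not show a fall: the median log2 changes of the members were 0.13 and 0.34. Runs without one array held fewer arrays, and those with brightness filters tested fewer genes. The cause was not tested for any of these counts. None of the 107 genes named by rule for the main sections changed direction past the threshold under any alternative run. Genes named only in the closing section or chosen afterwards were not followed through the alternatives. Without detection calls, signal over background limits what dim probes show.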

Other observations

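Genes ranked 9 to 20 by size of change, set by the same rule, included the lipid enzyme genes Scd, Pnpla3 and Me1 among the falls. Scd (stearoyl-CoA desaturase, which makes monounsaturated fatty acids) fell 2.26-fold from a log2 expression of 11.14 ± 0.05 to 9.97 ± 0.06 (SD, n = 3; limma adjusted p = 0.00141). Pnpla3 (a lipid droplet enzyme) fell 2.22-fold and Me1 (malic enzyme, a source of NADPH for lipid synthesis) 2.18-fold. Slc5a3, the myo-inositol transporter, fell 2.38-fold beside the taurine transporter Slc6a6; both substrates are organic osmolytes. Pmp2, a fatty acid binding protein of myelin, fell 2.27-fold, and Cmtm8, Map6d1, Hspb8 and Mgst1 fell 2.30-, 2.17-, 2.09- and 2.07-fold.

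Among the rises of those ranks, Cnn1 (calponin, of smooth muscle) rose 2.30-fold from 5.17 ± 0.25 to 6.38 ± 0.35 (SD, n = 3; limma adjusted p = 0.0142), beside Tagln and Ccn1. Nedd9 (a focal adhesion scaffold) rose 2.91-fold, Adgrg1 (an adhesion receptor of OPCs) 2.29-fold and A2m (alpha-2-macroglobulin, a protease inhibitor) 2.78-fold. Metrn (meteorin, a secreted factor of glia) rose 2.70-fold, Slc14a1 (a urea transporter of astrocytes) 2.33-fold, Grm5 (a glutamate receptor) 2.35-fold and Plce1 (a phospholipase) 2.27-fold.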
